A study of Homo sapiens with 6 samples.

How the data were processed

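Messenger RNA was profiled in 6 samples of SW480 cells, 3 with a lentiviral shRNA against YWHAE and 3 with a control shRNA; the vector also carries EGFP and puromycin resistance. Per the labels' protocols, total RNA was turned into biotin-labelled RNA with a 3' in vitro transcription kit and hybridised to Affymetrix PrimeView arrays. Samples were grouped by what the labels say they carried.

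The deposited table holds 49395 probe sets for 6 arrays on a log2 scale. The submitters' processing notes name RMA, MAS5 and Partek, with no versions or roles, and base 2 was taken from the usual output of RMA, since the sources used here do not state it. The median over the 6 arrays was within 0.001 of 0 for all 49395 probe sets, so the authors' values had been centred per probe set before deposit; who centred them and with what tool is not given in the sources used here. Centring removes expression levels: no detection call, floor or ranking by brightness could be made, and a change in a gene near background cannot be told from one in a bright gene. It places groups that differ on either side of 0 and leaves differences between arrays as they were. The values were used without further normalization. No per-sample column was left unmatched.

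Genes were named from the platform's annotation as paired with the probe sets. Of all probe sets 44988 had 1 gene symbol, 1832 had several, 2473 were unnamed and not controls, and 102 were controls, of which those of 1 transcript are not reported here. Entrez identifiers of 44961 of the 44988 were found in a RefSeq gene table (assembly GRCh38.p14), used for current names and for which genes neighbour each other. No build is named for the arrays, so no coordinates are given. Probe sets with several genes stayed out of the gene table, including 1 that lists YWHAE together with another gene. The log2 values of all probe sets naming a gene alone were averaged, giving 18132 genes, 6398 of them with 1 probe set and 11734 with several. For 234 called genes, 2 probe sets of the gene were called in opposite directions.

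Knockdown minus control was fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. At least 2-fold means an absolute log2 fold change of at least 1. The 31 gene lists (679 entries, 667 distinct symbols, 619 measured) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and with an estimated correlation and fry as alternatives. Few measured genes are shared between lists: 7 pairs of lists share 1 measured gene, and the mesenchymal and fibroblast lists share 3. Of the 31 lists 11 passed; 0 passed with an estimated correlation and 28 by the directional p of fry, which asks only whether a list's genes move one way. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

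The comparison, the lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule took YWHAE with all its probe sets, all 14-3-3 family members, the 10 largest changes in each direction among called genes whose groups do not overlap, up to 4 called members with the largest change for each list that passed and up to 2 for the others. Because the values are centred, several planned choices could not apply: the brightest probe set per gene gave way to the mean of the probe sets, which had been planned as the alternative, and a minimum level for named genes, a filter on dim genes, an intensity trend in the variance and pseudocounts were not run. Alternatives run were quantile normalization, median centring of arrays, array weights, the replicate number as a block, each array left out in turn, an adjusted p below 0.01 and a test against a fold change of 1.2. Chosen after seeing the data were the median of the probe sets, gene-specific probe sets (names ending in _at or _a_at) and a robust variance.

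The fit was tested on simulated data with the same 18132 genes and 6 arrays. It found 9 of 50 genes changed by 0.25 on the log2 scale (18%), 35 of 50 changed by 0.5 (70%), and 50 of 50 changed by 1 and by 2. Of 17897 unchanged genes 7 were called (0.0391%). Of 31 lists, 1 passed, the list that had been shifted by 0.3. The simulation changed far fewer genes than the 52.3% called in the data, so its rates need not hold there. It drew the genes independently, so it does not test camera on correlated genes.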

Results

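Gene expression was measured in SW480, an established human colon cancer cell line, on 6 Affymetrix PrimeView arrays, which read messenger RNA from near its 3' end with several probe sets for many genes. In 3 samples the cells carried a lentiviral short hairpin RNA (shRNA) against YWHAE, which encodes 14-3-3 epsilon, a member of a family of adaptor proteins that bind phosphorylated proteins. The other 3 samples carried a control shRNA. The comparison of knockdown with control asked which genes changed when YWHAE was silenced; the series title links the silencing to slower proliferation. Values were on a log2 scale and each probe set was centred on its median over the 6 arrays, so they give differences between samples and no expression level. The number of arrays limits the precision. Medians of the 6 arrays lay within 0.0133 of 0. Over all genes, the SD of the difference between 2 arrays was 0.123 to 0.156 within a group and 0.556 to 0.570 between groups.

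YWHAE was lower in all 3 knockdown samples. On 4 of its 5 probe sets the fall was 7.91-fold to 11.6-fold. Probe set 11753092_s_at read 1.72 ± 0.06 (SD, n = 3) in control and -1.75 ± 0.10 (SD, n = 3) in knockdown samples, a log2 fold change of -3.47. The others gave -3.54 (11753517_s_at), -2.98 (11753518_x_at) and -3.39 (11758309_s_at). The remaining probe set, 11762793_at, was 1.21-fold higher after knockdown (log2 fold change 0.27 ± 0.07 SE, limma adjusted p = 0.0110 over probe sets). Averaged over the 5 probe sets, YWHAE fell by 2.62 ± 0.06 (SE) on the log2 scale (limma adjusted p = 3.69e-08). Using 11762793_at alone, the choice of a rule that prefers probe sets made for a single gene, reversed the direction, to 0.27.

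Transcripts of the other 14-3-3 proteins moved in both directions, by less than YWHAE. YWHAH (14-3-3 eta) fell by 0.89 ± 0.06 (SE) on the log2 scale (adjusted p = 6.48e-06), lower on both of its probe sets. YWHAZ (14-3-3 zeta) rose 1.58-fold (log2 fold change 0.66 ± 0.05 SE, adjusted p = 1.10e-05) and was higher on all 6 of its probe sets. SFN (14-3-3 sigma, which restrains the cell cycle) rose 1.68-fold (0.75 ± 0.06 SE, adjusted p = 1.36e-05). YWHAQ (14-3-3 theta) rose by 0.26 on the log2 scale (adjusted p = 0.00427). YWHAB (14-3-3 beta) fell by 0.19 (adjusted p = 0.0265), a call lost without control replicate 3 (adjusted p = 0.0783), without knockdown replicate 1 (0.0930), without knockdown replicate 2 (0.0682) and with gene-specific probe sets (0.363). YWHAG (14-3-3 gamma) had a log2 fold change of 0.10 (adjusted p = 0.139), and its sign depended on the choice of probe sets. As a list, 3 of the 7 members rose and 3 fell, with the same counts when adjusted over the list alone. Its median was 0.10, its mean -0.28 and the camera test pointed down (adjusted p = 0.976; adjusted p = 0.985 with an estimated correlation). Quantile normalization and median centring of the arrays turned none of these 7 directions.

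**Figure D1:**
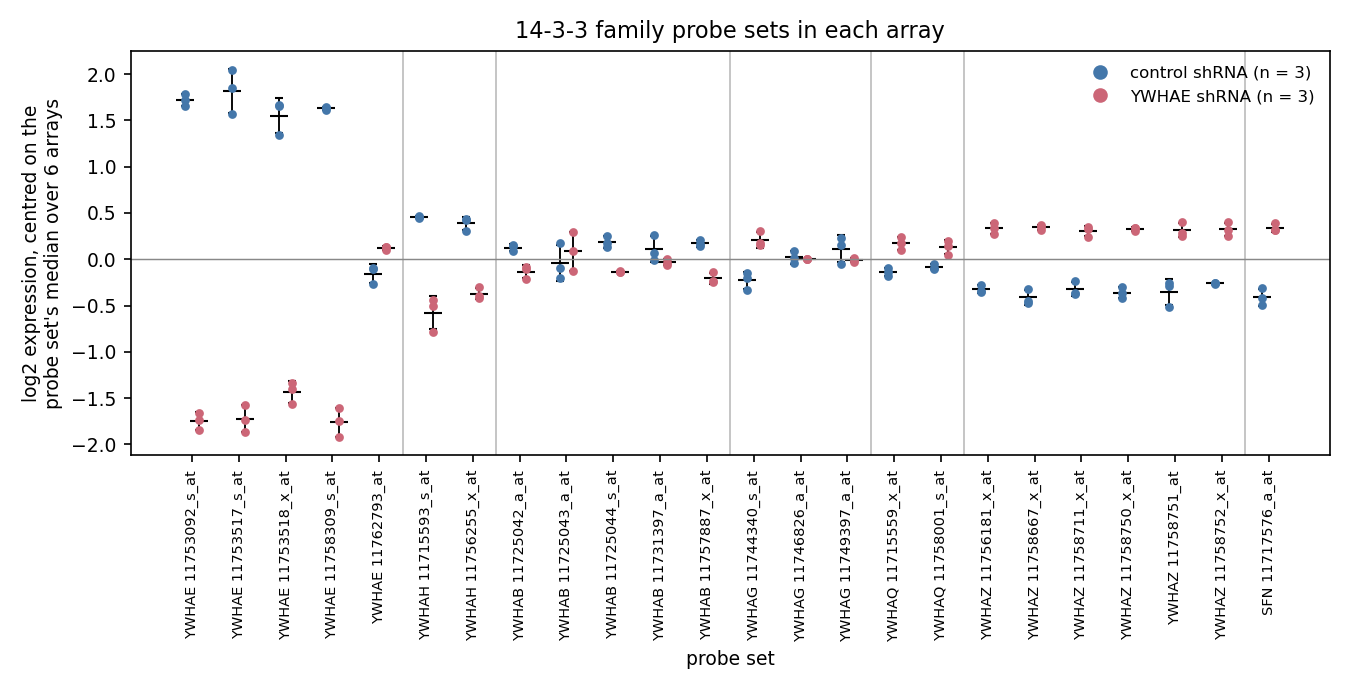
Log2 expression of every 14-3-3 family probe set in each of the 6 arrays, centred on the probe set's median; points are arrays and bars are the mean and SD of 3 arrays. On 4 YWHAE probe sets the control samples lie above 1.3 and the knockdown samples below -1.3, while 11762793_at and the YWHAZ probe sets are higher after knockdown.

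Outside this family, changes ran from FAM111B, which fell 30.7-fold, to DDIT4, which rose 27.9-fold, and the DNA replication list had the lowest median of 31 gene lists (-2.09). Of 18132 genes tested, 4967 were higher and 4513 lower after knockdown (limma, Benjamini-Hochberg adjusted p below 0.05), 52.3% of all genes. A change of at least 2-fold was reached by 692 higher and 683 lower genes. The 3 samples of each group did not overlap for 10755 genes (59.3%), where chance gives 10%. The median log2 fold change over all genes was 0.02. A test against a fold change of 1.2 left 2289 higher and 2433 lower genes. The control samples are labelled as re-analysed and carry another order number than the knockdown samples, so order number and group cannot be told apart. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

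FAM111B, which encodes a protease linked to DNA replication, was the gene that fell most, 30.7-fold (log2 fold change -4.94 ± 0.08 SE, adjusted p = 7.40e-09). TRIM2, a ubiquitin ligase gene, fell by 4.23. FGFBP1, whose protein releases fibroblast growth factors from the matrix, fell by 4.07. TSPAN8, a tetraspanin gene of the gut epithelium, fell by 3.49, and MYBL1, a transcription factor gene, fell by 3.48. DTL, MCM10, CCNE2, CDC6 and LGR5 completed the 10 largest decreases. The gene that rose most was DDIT4, an inhibitor of mTORC1 signalling, 27.9-fold higher (log2 fold change 4.80 ± 0.05 SE, adjusted p = 2.14e-09). IGDCC4, a cell-surface protein gene of the immunoglobulin superfamily, rose 18.4-fold, and IGFBP1, which binds insulin-like growth factors, rose by 4.17 on the log2 scale. MAP1B, a microtubule-associated protein gene, rose 17.2-fold, and ERRFI1, a feedback inhibitor of the EGF receptor, rose 14.6-fold. INHBE, an inhibin subunit gene, rose 13.3-fold, MYZAP, a cell-junction protein gene, 12.8-fold and RGS10, a regulator of G-protein signalling, 12.5-fold. DUSP5 and CDKN2B, at log2 fold changes of 3.76 and 3.46, completed the 10 largest increases. For these 20 genes the SE of the log2 fold change was 0.05 to 0.13 and the highest adjusted p was 9.61e-08.

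**Figure D2:**
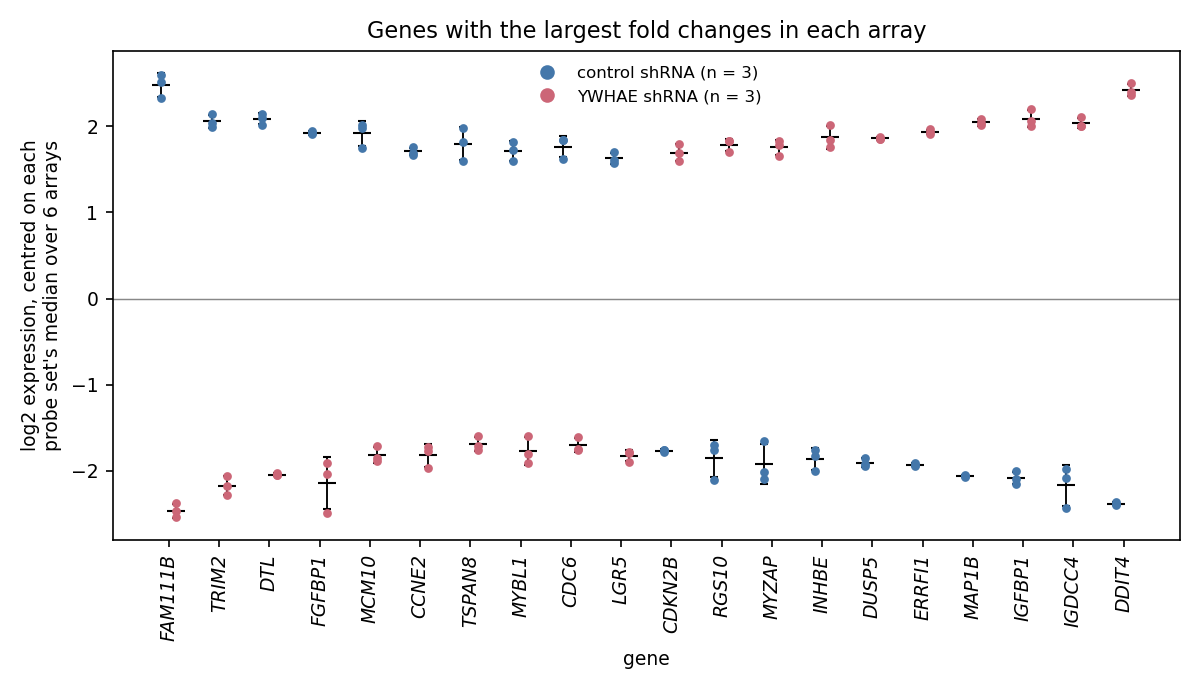
Log2 expression of the 10 genes that fell most and the 10 that rose most, in each array, centred on each probe set's median; points are arrays and bars are the mean and SD of 3 arrays. The groups are separate for all 20 genes, from FAM111B at -4.94 to DDIT4 at 4.80.

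All 35 measured genes of the DNA replication list fell, with a median log2 fold change of -2.09, while the mitosis list was mixed. The 35 were called both over all genes and adjusted over the list alone (camera adjusted p = 1.13e-22; adjusted p = 0.113 with an estimated correlation). Among them RFC5 fell by 1.05 as the mean of 4 probe sets, some of which were called in opposite directions. DTL, a substrate adaptor that limits origin re-firing, fell by 4.13 ± 0.05 (SE). MCM10, a replication initiation factor, fell by 3.73 ± 0.08. CCNE2, the S-phase cyclin E2, fell by 3.53 ± 0.07. CDC6, which loads the replicative helicase, fell by 3.47 ± 0.08. In the mitosis list 18 of 33 genes fell, 9 rose and 6 were not called (18 lower and 10 higher adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.126; adjusted p = 0.576 with an estimated correlation). CDK1, the mitotic kinase, fell by 1.46 ± 0.07, and MAD2L1, a spindle checkpoint gene, fell by 1.42 ± 0.06. HMMR, a spindle protein gene, and CCNB2, cyclin B2, were chosen after their values were seen: they rose by 1.23 and 1.02 on the log2 scale. The mean of the DNA replication list less that of the mitosis list was 0.99 ± 0.06 (SD, n = 3) in control and -0.97 ± 0.01 (SD, n = 3) in knockdown samples (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 samples allow). The 3 probe sets of 18S ribosomal RNA moved with the groups as well, from -0.49 ± 0.24 (SD, n = 3) in control to 0.37 ± 0.10 (SD, n = 3) in knockdown samples, beside this list and every list given next. The 27 bacterial poly-A control probe sets went the other way, from 0.12 ± 0.13 (SD, n = 3) to -0.10 ± 0.07 (SD, n = 3).

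Most genes of the ribosome biogenesis, cholesterol synthesis and proteasome lists were lower after knockdown. Of 21 ribosome biogenesis genes 18 fell, 0 rose and 3 were not called (19 lower adjusted over the list alone), with a median of -0.76 (camera adjusted p = 9.34e-08; adjusted p = 0.113 with an estimated correlation). UTP20, needed to process the small-subunit rRNA, fell by 1.92 ± 0.12 (SE), and NOP56 and NOP58, core proteins of rRNA-modifying particles, fell 2.30-fold and 2.17-fold. BOP1, a large-subunit assembly factor, fell by 1.10 ± 0.05. Of 18 cholesterol synthesis genes 16 fell and 2 were not called, with 16 also adjusted over the list alone, and a median of -0.79 (camera adjusted p = 9.34e-08; adjusted p = 0.141 with an estimated correlation). IDI1, an isomerase of the isoprenoid pathway, fell by 2.07 ± 0.08, ACAT2, the cytosolic acetyl-CoA acetyltransferase, fell by 1.60 ± 0.05 and HMGCS1, the HMG-CoA synthase, fell by 1.41 ± 0.05. INSIG1, a feedback regulator of the pathway, fell by 1.06 ± 0.05. Of 24 proteasome genes 15 fell, 2 rose and 7 were not called, with the same counts adjusted over the list alone, and a median of -0.26 (camera adjusted p = 0.00155; adjusted p = 0.258 with an estimated correlation). The ATPase subunit genes PSMC4, PSMC2 and PSMC3 had log2 fold changes of -0.81, -0.80 and -0.75, whereas PSMD2, a scaffold subunit gene, rose 1.83-fold.

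Genes of the amino acid and ATF4 response rose, as did genes of hypoxia and glycolysis. Of 21 genes of the ATF4 list, which are switched on when translation is restrained under stress, 17 rose, 2 fell and 2 were not called (18 higher and 3 lower adjusted over the list alone), with a median of 1.01 (camera adjusted p = 5.51e-07; adjusted p = 0.113 with an estimated correlation). Besides DDIT4 at 4.80, SESN2, a leucine sensor and mTORC1 inhibitor, rose 5.24-fold (log2 fold change 2.39 ± 0.07 SE). DDIT3, the stress transcription factor CHOP, rose 4.50-fold (2.17 ± 0.06 SE), and TRIB3, a pseudokinase that restrains AKT, rose 4.42-fold (2.14 ± 0.05 SE). Of 24 hypoxia and glycolysis genes 20 rose, 0 fell and 4 were not called (20 higher and 1 lower adjusted over the list alone), with a median of 0.60 (camera adjusted p = 5.51e-07; adjusted p = 0.249 with an estimated correlation). NDRG1, a hypoxia-induced stress gene, rose 6.11-fold (2.61 ± 0.09 SE) and ADM, the peptide hormone adrenomedullin, rose 3.98-fold (1.99 ± 0.05 SE). VEGFA, the angiogenic growth factor, rose 3.71-fold (1.89 ± 0.05 SE) and PFKFB4, which regulates glycolysis, rose 3.00-fold (1.58 ± 0.05 SE).

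Most genes of the ERK, NF-kB and FOXO lists rose. Of 21 genes of ERK output and the immediate early response 17 rose, 3 fell and 1 was not called (18 higher and 3 lower adjusted over the list alone), with a median of 0.71 (camera adjusted p = 6.94e-05; adjusted p = 0.346 with an estimated correlation). DUSP5 and DUSP4, phosphatases that switch ERK off, rose by 3.76 ± 0.05 (SE) and 1.93 ± 0.12 on the log2 scale, and the immediate early factors FOS and EGR1 rose by 1.81 ± 0.07 and 1.40 ± 0.09. Of 21 NF-kB and inflammatory genes 12 rose, 2 fell and 7 were not called (13 higher and 3 lower adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.00789; adjusted p = 0.180 with an estimated correlation). The neutrophil chemokines CXCL3 (4.45-fold), CXCL8 (4.0-fold), CXCL1 (3.67-fold) and CXCL2 (2.74-fold) rose, of which CXCL1, CXCL2 and CXCL3 are near-identical copies that the probes may not separate. Of 18 FOXO target genes 12 rose, 2 fell and 4 were not called (13 higher and 4 lower adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.00848; adjusted p = 0.180 with an estimated correlation). GADD45A, a growth arrest gene, rose 4.40-fold, KLF6, a zinc-finger factor, 4.07-fold, FBXO32, the ubiquitin ligase atrogin-1, 3.12-fold and CCNG2, an atypical cyclin of quiescent cells, 2.59-fold.

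CDKN2B and CDKN1B, inhibitors of cyclin-dependent kinases (CDKs), rose, as did the BH3-only death genes BBC3 and PMAIP1, while other members of their lists fell. Of 21 p53 targets and CDK inhibitors 12 rose, 5 fell and 4 were not called, with the same counts adjusted over the list alone, and a median of 0.45 (camera adjusted p = 0.0355; adjusted p = 0.432 with an estimated correlation). CDKN2B (p15), an inhibitor of CDK4 and CDK6, rose by 3.46 ± 0.06 (SE) on the log2 scale, and CDKN1B (p27), which inhibits cyclin E complexes, rose by 1.89 ± 0.09. Its other leading members were SESN2, which the ATF4 list also holds, and GADD45A, which the FOXO list also holds. CDKN2D (p19), another CDK inhibitor chosen after its value was seen, fell by 0.35 (adjusted p = 0.0104). Of 18 pro-apoptotic genes 11 rose, 3 fell and 4 were not called, with the same counts adjusted over the list alone, and a median of 0.31 (camera adjusted p = 0.0477; adjusted p = 0.249 with an estimated correlation). BBC3 (PUMA) and PMAIP1 (NOXA), BH3-only activators of cell death, rose 2.46-fold and 2.40-fold, and CASP8, the initiator caspase of death receptors, rose 1.84-fold. CYCS, cytochrome c, fell by 0.94, and BID, a BH3-only gene chosen after its value was seen, fell by 0.55 (adjusted p = 2.07e-05). The p53 list lost its call without knockdown replicate 3 (adjusted p = 0.0920) and with array weights (0.0678), over a range of 0.0114 to 0.0920. The pro-apoptotic list lost it without control replicate 2 (adjusted p = 0.0513), without knockdown replicate 3 (0.0748), with array weights (0.0626) and with the median of probe sets (0.0624), over a range of 0.0367 to 0.0748.

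**Figure D3:**
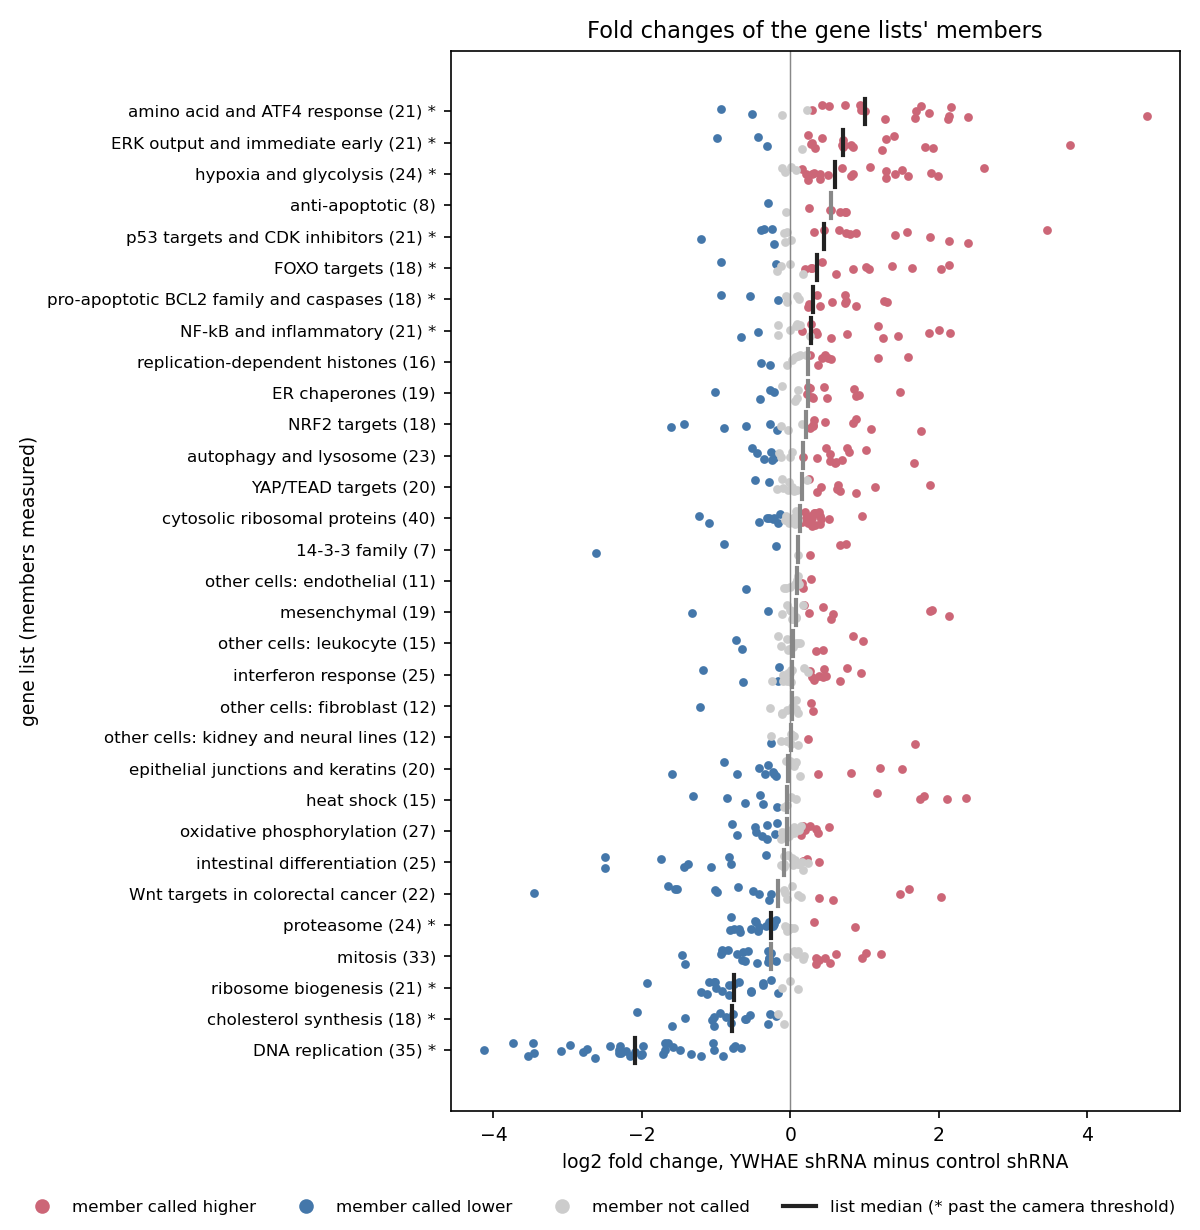
Log2 fold change, knockdown minus control, of each measured member of the 31 gene lists, coloured by call. Vertical bars are list medians and asterisks mark the 11 lists past the camera threshold at the preset correlation. With an estimated correlation 0 lists pass. The DNA replication list has the lowest median (-2.09) and all its members lie below 0, and the ATF4 list has the highest (1.01).

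Lists of colon identity and of cell state were mixed and did not pass the list test, although single members moved far. Of 22 Wnt targets 11 fell and 5 rose (11 lower and 6 higher adjusted over the list alone; median -0.17, camera adjusted p = 0.0833). LGR5, the intestinal stem cell receptor, fell by 3.45 ± 0.06 (SE) and TNFRSF19, a TNF receptor family gene, rose by 2.03 ± 0.07. Of 25 intestinal differentiation genes 9 fell and 3 rose, also adjusted over the list alone (median -0.08, camera adjusted p = 0.0778). CEACAM5, the carcinoembryonic antigen, and CDX2, the master transcription factor of the intestine, fell, with log2 fold changes of -2.50 ± 0.05 (SE) and -2.49 ± 0.07. Of 20 epithelial junction and keratin genes 9 fell and 4 rose, also adjusted over the list alone (median -0.03, camera adjusted p = 0.541). CDH1 (E-cadherin) fell by 1.59 ± 0.07 and CLDN4, a tight junction claudin, rose 2.84-fold. Of 19 mesenchymal genes 8 rose and 2 fell, also adjusted over the list alone (median 0.08, camera adjusted p = 0.0932). VIM (vimentin) and ZEB1, a repressor of E-cadherin, rose by 2.14 ± 0.05 and 1.91 ± 0.06. Without knockdown replicate 1 the intestinal list passed (camera adjusted p = 0.0395, range over the 13 refits 0.0395 to 0.105). With an estimated correlation and all 6 arrays its camera adjusted p was 0.346.

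Stress and housekeeping lists other than those above also did not pass. Of 19 endoplasmic reticulum (ER) chaperone genes 11 rose and 4 fell, also adjusted over the list alone (median 0.23, camera adjusted p = 0.0778); HERPUD1, an ER degradation gene, rose by 1.48 and DNAJC3, an inhibitor of the kinase PERK, fell by 1.01. Of 15 heat shock genes 5 rose and 6 fell, also adjusted over the list alone, with a median of -0.04 but a mean of 0.36 and a camera test pointing up (adjusted p = 0.925). The inducible chaperones HSPA1B and HSPA6, which have near-identical copies, rose by 2.36 and 2.12. Of 18 NRF2 targets 9 rose and 6 fell (10 and 6 adjusted over the list alone; median 0.21, camera adjusted p = 0.635). SLC7A11, the cystine transporter, rose by 1.76 and AKR1C1, an aldo-keto reductase with near-identical copies, fell by 1.60. Of 23 autophagy and lysosome genes 12 rose and 7 fell, also adjusted over the list alone (median 0.18, camera adjusted p = 0.174), with WIPI1 and GABARAPL1, both of autophagosome formation, higher by 1.66 and 1.01. Of 25 interferon response genes 10 rose and 4 fell (10 and 5 adjusted over the list alone; median 0.03, camera adjusted p = 0.416). MX2, an antiviral GTPase, rose by 0.96 and IFI6, an interferon-induced mitochondrial protein gene, fell by 1.17. Of 20 YAP/TEAD targets 9 rose and 2 fell, also adjusted over the list alone (median 0.16, camera adjusted p = 0.110), with AXL, a receptor tyrosine kinase, and NT5E (CD73) higher by 1.88 and 1.15. Of 8 anti-apoptotic genes 6 rose and 1 fell, also adjusted over the list alone (median 0.54, camera adjusted p = 0.0764), with the caspase inhibitor XIAP and BCL2L1 (BCL-XL) higher by 0.75 and 0.74.

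Of 40 genes of cytosolic ribosomal proteins, the structural parts of the ribosome, 20 rose and 9 fell, also adjusted over the list alone (median 0.13, camera adjusted p = 0.110). RPL14 and RPS14 fell, at -1.22 and -1.09, and such genes have many processed copies that probes may not separate. Of 27 oxidative phosphorylation genes 7 rose and 9 fell, also adjusted over the list alone (median -0.04, camera adjusted p = 0.540), with CYC1, of complex III, and NDUFV2, of complex I, lower after knockdown at -0.78 and -0.72. Of 16 replication-dependent histone genes 8 rose and 2 fell, also adjusted over the list alone (median 0.24, camera adjusted p = 0.0668). H2AC6 and H1-4, histone genes with close copies, rose by 1.59 and 1.18. The histone list passed without knockdown replicate 1 (camera adjusted p = 0.0383, range over the 13 refits 0.0383 to 0.101). With an estimated correlation and all 6 arrays its camera adjusted p was 0.312.

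Lists of markers of other cell types did not pass the camera test. Of 12 fibroblast markers 2 rose and 1 fell (median 0.03, mean -0.07, with camera pointing down, adjusted p = 0.948); LUM, a matrix proteoglycan gene, fell by 1.22 and ACTA2, smooth muscle actin, rose by 0.30, a call lost with gene-specific probe sets (adjusted p = 0.613). Of 15 leukocyte markers 4 rose and 2 fell (median 0.03, camera adjusted p = 0.635), with CD68, a lysosomal macrophage marker, and LCP1, an actin-bundling protein gene, higher by 0.98 and 0.84. Of 11 endothelial markers 3 rose and 1 fell (median 0.09, camera adjusted p = 0.823); EGFL7, a vessel matrix gene, fell by 0.59. ROBO4, a vascular guidance receptor, rose by 0.28 (adjusted p = 0.0277), a call lost without any 1 of the arrays except knockdown replicate 3 (adjusted p = 0.0521 to 0.0673), with the median of probe sets (0.0991) and with gene-specific probe sets (0.127). Without knockdown replicate 2 the log2 fold change of ROBO4 was 0.18. Of 12 kidney and neural markers 2 rose and 1 fell (median 0.00, camera adjusted p = 0.948), with TUBB3, a neuronal tubulin, higher by 1.68 and CHGA, chromogranin A, lower after knockdown at -0.27. The counts of these 4 lists were the same adjusted over the list alone.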

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

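The count of splits of the samples and the windows of neighbouring genes were planned before their results were seen; the tests on hybridisation controls, the DNA replication and mitosis lists, the 3' and 5' control probe sets, the interferon list and the ER chaperone list were chosen only after the results were seen.

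Control probe sets that lie outside the gene comparison differed between the groups. Those of 18S ribosomal RNA were higher after knockdown by 0.86 on the log2 scale as a mean of 3 probe sets, and those of 28S by 0.23. The 27 bacterial poly-A controls were lower after knockdown, with a mean difference of -0.23 and a range of -0.63 to 0.02. Of 2473 probe sets with no gene name, 599 were higher and 552 lower after knockdown (limma, Benjamini-Hochberg adjusted p below 0.05), with 108 and 91 of them changed by at least 2-fold.

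Calls covered 9480 of 18132 genes. Among the 10 splits of the 6 arrays into 3 and 3, 1 called as many, the real one, and the highest other split called 0. Each other split mixes the groups, so the difference between groups adds to its spread and holds its calls down. For that reason, and because 10 splits are too few for a share under 0.05, the count does not decide the matter. Over 331 windows of 51 neighbouring autosomal genes the highest absolute median was 0.208. It was 0.187 once the median of all genes in windows was taken off, under the bound of 0.3. This argues against copy number differences between the cell stocks that shift most genes of such a window by 0.3 or more. Smaller or shorter differences stay open. The SD of the window medians was 0.0611 against at most 0.0513 in 1000 shuffles, and these windows cannot tell smaller from shorter differences. Shuffling also separates neighbouring genes that change together for other reasons, so the larger SD is not by itself a sign of copy number. The 18 hybridisation controls differed by at most 0.239, so hybridisation and scanning did not shift these controls by 2-fold. Effects particular to other probe sets stay open, since the controls do not read them. For calls of smaller size hybridisation and scanning also stay open, since some of these controls passed the threshold themselves. AFFX-BioB-5_at differed by -0.239 (limma adjusted p = 0.00842 over all probe sets) and AFFX-r2-Ec-bioD-5_at by 0.239 (adjusted p = 0.0135). The mean of the 18 controls differed by -0.0141. The knockdown itself may account for the calls, but the order number divides the samples in the same way and cannot be told apart from it, and the labels do not tell whether culture or labelling also differed.

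The DNA replication list fell further than the mitosis list. Fewer cycling cells with an unaltered mix of phases would by themselves raise no mitosis gene, and 9 of 33 were called higher. Over all genes 4967 of 18132 were called higher, a like share. The count may thus reflect changes across the whole array, and it does not decide the matter. Such a fall in cycling cells would, however, lower both lists alike, and the medians were -2.09 for DNA replication and -0.26 for mitosis. The mean of the first list less that of the second went from 0.99 ± 0.06 (SD, n = 3) in control to -0.97 ± 0.01 (SD, n = 3) in knockdown samples. This argues against fewer cycling cells as the only cause of the gap. Fewer cycling cells beside another change stay open. RNA quality stays open: the 3' minus 5' difference of the ACTB and GAPDH controls moved by at most 0.0933 in size. The 18S controls, however, moved by 1.24 at the 3' and 0.66 at the 5' end. Bacterial poly-A controls were uneven at these ends: LysX moved by -0.17 and -0.63 and PheX by -0.09 and -0.40. TrpnX moved by -0.36 and -0.05, ThrX by -0.21 and -0.20 and DapX by 0.02 and -0.08. Being bacterial, they do not show the quality of the cells' own RNA. A shift of the cells out of S phase, or a direct fall of replication transcripts, may also account for it, and neither was tested.

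The amino acid and ATF4 response list rose. An interferon response to the hairpin stays open. The list had a median of 0.030 (0.000241 to 0.189 over the alternatives) and no camera call. Of its 25 members 10 rose, among them MX2, IRF9 and ISG15, and 4 fell, among them IFI6 by 1.17. Over all genes 4967 of 18132 were called higher. The directional test of fry pointed up (adjusted p = 0.000321), but fry passed 28 of 31 lists, so it does not set this list apart. Control samples carried an shRNA as well, so a response shared by both groups would not show. An unfolded protein response in the ER stays open: the ER chaperone list had a median of 0.235 and 11 of 19 genes higher, between what that explanation requires and what it forbids. Nutrient supply could also raise these genes, and was not tested.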

How the results depend on the processing

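The settings on the median of probe sets, gene-specific probe sets and a robust variance were chosen only after the data were seen. Of 86 alternative values of the YWHAE fold change and of the counts of genes and lists, 81 kept their direction and their side of the threshold or stayed within 1.5 times. With gene-specific probe sets YWHAE reversed to 0.27 (adjusted p = 0.00663), because that rule leaves 11762793_at alone; with the median of probe sets it was -3.24. YWHAG, not called, turned to -0.0156 with the median of probe sets and -0.0727 with gene-specific probe sets. The test against a fold change of 1.2 gave 2289 higher and 2433 lower genes. Of the lists, 0 passed with an estimated correlation and 28 with fry; the estimate rests on the few residual degrees of freedom of 6 arrays. Leaving out each array in turn gave 4281 to 5058 higher and 4108 to 4397 lower genes, 9 to 13 lists past the threshold and YWHAE at -2.68 to -2.57. Across the refits 8237 to 9423 of the 9480 calls were shared with the same sign, and opposite calls numbered 5 with the median of probe sets, 15 with gene-specific probe sets and 0 otherwise. Of 98 called named genes 94 kept call and sign under all 13 alternatives; the exceptions were YWHAE, YWHAB, ACTA2 and ROBO4. Of the 11 lists that passed, 9 passed in all 13.

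Replicate numbers did not pair the samples: residuals of same-numbered arrays correlated at -0.101 to 0.0552, against -0.106 to 0.116 for other pairs across groups. With the replicate block 4810 genes were higher and 4395 lower, 11 lists passed and YWHAE stayed at -2.62. The filter on dim genes, the intensity trend and the pseudocounts were not run, since centred values hold no level, and signal over background is therefore unknown.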

Other observations

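The genes given here were chosen only after their values were seen, and no test was planned for them. Genes of the HOXB cluster, which set positional identity in development, rose together: 9 of 10 measured members were higher after knockdown and 0 lower (limma, Benjamini-Hochberg adjusted p below 0.05), with a median log2 fold change of 1.14. HOXB9 rose by 2.37 ± 0.15 (SE), HOXB6 by 2.19 ± 0.09 and HOXB2 by 2.13 ± 0.16. In the HOXC cluster 4 of 9 were higher and 1 lower, in HOXD 1 of 7 was higher and in HOXA the 1 measured member was higher. The difference between clusters was not tested.

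Further single genes also changed, and no enrichment was tested for them. EXO1, an exonuclease of DNA repair, fell by 2.67 on the log2 scale and CLSPN, a replication checkpoint adaptor, fell by 2.37. BARD1, the partner of BRCA1, fell by 2.26, BRCA1 fell by 1.38 and CHEK1, the replication checkpoint kinase, fell by 1.56. RAD51AP1, a recombination factor, fell by 2.06. CDC25A, a phosphatase that activates CDKs, fell by 3.26, GMNN, the licensing inhibitor geminin, fell by 2.65, CDK6 fell by 2.31 and SKP2, which targets p27 for degradation, fell by 1.37. ARRDC4, an arrestin-like gene that responds to glucose, fell by 3.12, and its relative TXNIP, which the FOXO list holds, fell by 0.94. FASN, the fatty acid synthase, and SCD, a fatty acid desaturase, had log2 fold changes of -0.92 each. TUBA1A, an alpha tubulin with close copies, rose by 3.27, CRMP1, of axon guidance, rose by 2.90, TAGLN3 rose by 2.69 and TUBB2A, a beta tubulin with close copies, rose by 2.23. PLAU, the urokinase gene, rose by 2.95 and ITGA2, an integrin that binds collagen, rose by 2.81.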
